A study of Homo sapiens with 12 samples.

How the data were processed

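HepG2 is an established human liver carcinoma cell line that responds to interleukin-6 (IL-6), the cytokine that drives the hepatic acute phase response. The labels describe 12 expression arrays, hybridised with phycoerythrin-labelled material from total RNA, in 6 groups of 2. HepG2 cells and HepG2-ΔSrc1 cells (called dSrc1 here), in which the nuclear receptor coactivator SRC-1, the product of NCOA1, was silenced by a stably expressed shRNA, were left untreated or received 10 ng/ml IL-6 for 1 h or 4 h. The labels carry no replicate numbers, so replicates 1 and 2 of a group only follow the order in which the arrays are listed. The series text states that each experiment was done in replicate but not whether the 2 arrays of a group came from separate cultures. Every p-value here therefore measures at most the spread between these arrays. That of Fisher's exact test, which is taken over genes, does not measure it. No line with a control shRNA and no culture handled without IL-6 at 1 h or 4 h is among the arrays.

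The deposited table holds the signal intensity of 22283 probe sets in each of the 12 arrays on a linear scale. Per the submitters' processing notes the signals came from MAS5, whose version is not stated. The 2% trimmed mean of the deposited intensities was 500.167 to 500.205 in the 12 arrays, and the table was therefore taken as already scaled and was not scaled again. All 12 columns were used. Gene symbols came from the platform's probe table, brought up to date through the Entrez gene identifiers it lists. Of the probe sets, 19071 had 1 symbol, 1043 had several and 2169 had none, and 19059 symbols were looked up by identifier. Gene positions are not given, because the deposited files name no genome build.

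An offset of 33, the 20th percentile of all signals, was added before the log2 was taken. The 68 control probe sets were left out, and a probe set was kept when its signal reached 108.3, the 40th percentile, in at least 2 arrays. This kept 16284 probe sets, of which 14225 had a symbol. The probe set of a gene with the highest mean log2 signal stood for the gene, which gave 9688 genes, and counts of genes and gene lists use these. Called probe sets that do not stand for a gene are left out of the counts of genes. The number of arrays limits the precision of every value, because each group mean rests on 2 arrays.

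A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 (lmFit, then eBayes with a trend on the mean signal) under R 4.3.3. All groups share the estimate of the spread, which had 6 residual degrees of freedom and a prior of 11.7. The median residual SD was 0.323 on the log2 scale. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the probe sets kept, and an adjusted p under 0.05 was called. "Rose", "fell" and "changed" are used for called differences. The 12 contrasts were IL-6 at 1 h and at 4 h in each line, 4 h against 1 h in each line, the mean response of both lines at each time, the interaction of line and IL-6 at each time (the response in dSrc1 minus that in HepG2), and dSrc1 against HepG2 in untreated cells and as the mean of 3 treatments. The number behind "SE" is the standard error of the log2 difference from limma, and "SD" is the standard deviation between arrays.

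There were 23 gene lists with 424 entries in all, drawn up from general knowledge, and some genes stand in several lists. The STAT3 early target and immediate early lists share FOS, JUNB, EGR1, IER3, KLF6, ZFP36 and MYC. Each list was tested against all other genes with camera from limma with an inter-gene correlation of 0.01, adjusted over the 23 lists of a contrast. Camera with the correlation estimated from the data served as the alternative. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the measured members of a list. The size of the response in dSrc1 relative to HepG2 was the median, over the genes called for the mean of both lines, of the dSrc1 response minus the HepG2 response, each given the sign of the mean response, and was tested with the rotation test fry from limma, adjusted over 6 tests. This set of genes was chosen on the mean of the lines and not on their difference. Overlap between lines was tested with Fisher's exact test (one-sided) over the 9688 genes. For NCOA1 the line labels were also permuted exactly over the 462 splits of the 12 arrays into 6 and 6.

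The genes named were NCOA1 with all its probe sets and members of the lists as examples. In each contrast the 10 largest rises and the 10 largest falls among called genes were named too (12 and 12 for the mean line difference). Between single groups the arrays of these genes did not overlap. For the means, the difference only had the same sign in each line or treatment, and the interaction had no such rule. Where fewer than 5 genes were called, those with the 5 smallest p-values were named. Not every gene the rule allows is printed. Another probe set of SOCS3, a probe set without a symbol and the genes of the line comparison in IL-6-treated cells were chosen after their values were seen.

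The sample groups, tests, gene lists, thresholds and most alternatives were fixed before the data were examined. These alternatives were an offset of 16.5 or 66 or none with a floor of 1, quantile normalization, a common median for all arrays, no filter, a filter at the 60th percentile (256.9), no trend, array weights, only the 6 arrays of a line, only the untreated arrays and those of the same time, at least 2-fold change as well, an adjusted p under 0.1, the mean of all probe sets of a gene, leaving out the probe sets with the suffix _x_at or _s_at, an estimated correlation, other gene sets for the response size, and each of the 12 arrays left out in turn. Leaving out 2 arrays that stand apart in the principal components, the line difference in IL-6-treated cells, and quantile-normalized medians of 3 liver lists were added after seeing the data.

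Recovery was tested on simulated data in which 200 of 16284 probe sets were changed, 5 times over. At 2-fold, 31.6% were recovered for IL-6 at 4 h in HepG2, 57.6% for the mean of both lines at 4 h and 72.4% for the mean line difference. At 4-fold these shares were 77.6%, 92.8% and 98.4%. The calls included 5.39%, 5.32% and 4.96% unchanged probe sets, respectively. With no change added, no probe set was called in 5 runs, and 4 of 115 list tests of the 4 h interaction had an unadjusted camera p under 0.05, of which 2 were called after adjustment. With equal responses in both lines, 2 of 20 runs of the response size test had a p under 0.05, and the largest median difference was 0.0423 in size. In the simulated data each value was drawn independently, with no correlation between genes and no array that stood apart. The error rates of the list and response size tests may therefore differ in the real arrays. There, 73 list tests were called at the preset correlation and 33 with an estimated one.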

Results

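Messenger RNA was measured on 12 arrays from HepG2 and dSrc1 cells that were untreated or had received 10 ng/ml IL-6 for 1 h or 4 h, with 2 arrays in each of the 6 groups. The median signal of an array lay between 150.1 and 186.6, and the Spearman correlation of the 2 arrays of a group, across probe sets, between 0.910 and 0.941. The first principal component carried 17.2% and the next 14.9% of the variance, and HepG2 untreated replicate 1 and dSrc1 1 h replicate 2 stood apart from the other arrays on the latter.

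The first comparison asked how far the shRNA had lowered NCOA1, the transcript of SRC-1. NCOA1 was lower in dSrc1 on all 4 of its probe sets. On the probe set whose arrays did not overlap between the lines the signal was 160.4 ± 16.4 in HepG2 and 31.7 ± 16.1 in dSrc1 (SD, n = 6 each). The dSrc1 mean lies below the offset of 33 and is not above background, so the share left cannot be read from it. On the probe sets with the suffix _s_at and _x_at, the dSrc1 mean was 48.4% and 70.4% of the HepG2 mean. The 6 dSrc1 arrays, at 11.4 to 60, lay below the 6 HepG2 arrays, at 134 to 179.5. The log2 difference, as the mean of 3 treatments, was -1.61 (SE 0.28), with a limma adjusted p of 0.0297. The exact permutation p was 0.00217, the smallest that the 462 splits can give, and 0.00866 when adjusted over the 4 probe sets. On the other 3 probe sets, of which the last 2 carry the suffix _s_at and _x_at, the log2 difference was -1.37, -0.94 and -0.47. The first of these also had a dSrc1 mean, 24.6, below the offset. Its size and that of the called probe set depend on the offset, and with none and a floor of 1 they were -2.81 (adjusted p = 0.212) and -2.50 (adjusted p = 0.0404). At the offset of 33 the other 3 probe sets did not pass limma (adjusted p = 0.198, 0.111 and 0.283). Their exact permutation p-values of 0.00649, 0.00649 and 0.00866 were each 0.00866 after adjustment. The limma call for NCOA1 was lost when any of 9 arrays was left out, which were the 6 HepG2 arrays, both untreated dSrc1 arrays and dSrc1 4 h replicate 1 (log2 difference -1.55 to -1.67, adjusted p = 0.0575 to 0.123), and with a common median (-1.60, adjusted p = 0.054).

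**Figure D1:**
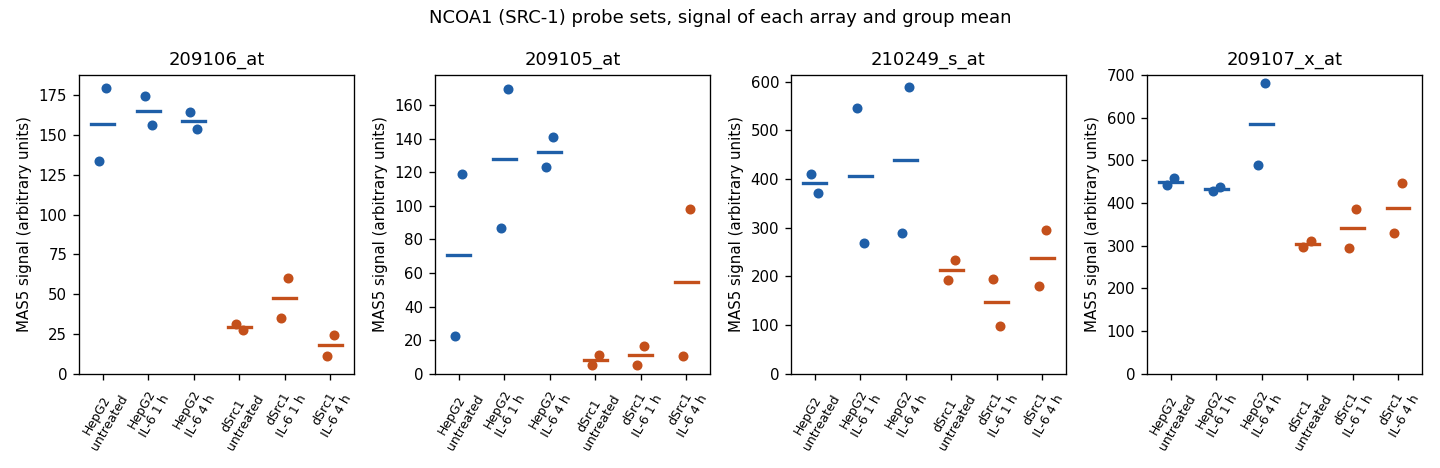
Signal of NCOA1 on each of its 4 probe sets in the 12 arrays. Points are arrays and bars are group means. In the panel whose arrays do not overlap, the 6 dSrc1 arrays lie between 11.4 and 60, below the 6 HepG2 arrays.

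The response of HepG2 to IL-6 at 1 h addressed the early targets of the cytokine. Among the called genes, each by the probe set that stands for it, metallothionein genes, whose products bind zinc and copper, had the 6 largest rises. The MT1F signal went from 225 ± 84.7 in untreated cells to 5512 ± 724 at 1 h (SD, n = 2 each), a log2 change of 4.46 (SE 0.28, limma adjusted p = 7.9e-08). MT1E, MT1G, MT1H, MT1X and MT2A rose by log2 3.16, 3.10, 2.99, 2.73 and 2.01. SOCS3, a feedback inhibitor of the JAK-STAT pathway, rose from 17.0 ± 6.86 to 715 ± 195 on 1 of its 3 probe sets (log2 3.89, SE 0.53, limma adjusted p = 0.0011). That probe set was chosen after its values were seen, and its untreated signal lies below the offset of 33, so the size of the rise depends on the offset. On the probe set that stands for SOCS3 under the selection rule the change was -0.17 (adjusted p = 0.95), and on the last it was 1.03 (adjusted p = 0.68). CEBPD, which encodes the acute phase transcription factor C/EBPδ, rose by 1.53 (SE 0.19, adjusted p = 3.0e-04). JUNB rose by 1.40 and IER3 by 0.99, both immediate early genes. The peptide hormone gene ADM rose by 1.88, the trafficking adaptor gene AP1M2 by 1.55 and the glutathione transferase gene GSTA1 by 1.44. G6PC1, the glucose-6-phosphatase gene of gluconeogenesis, fell by 1.88 (SE 0.38, adjusted p = 0.043). The stress gene DDIT4 changed by -2.20, IGFBP3 by -1.99, the lipid metabolism regulator ANGPTL8 by -1.98 and the secreted factor STC2 by -1.59. HOXD1, PNRC1, FGL1, the complement gene C5 and PLOD2 changed by -1.54, -1.10, -1.05, -1.01 and -0.96. In all, 45 of 16284 probe sets were called by limma, 29 up and 16 down. Those that stand for a gene gave 33 genes, 21 up and 12 down, of which 26 changed at least 2-fold. SOCS3 is not among the 33, because the probe set that rose does not stand for it. The share rising was 64.4% of the probe sets called and 76.9% of those called with a common median. The count was 20 without HepG2 untreated replicate 1, 19 without either HepG2 1 h array and 70 without either dSrc1 1 h array. Of the 33 genes, 9 stayed called whichever array was left out, which were ADM, AP1M2, CEBPD, MT1E, MT1F, MT1G, MT1H, MT1X and MT2A. The SOCS3 call was lost without HepG2 1 h replicate 2 (log2 3.62, adjusted p = 0.0684).

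Among the preset lists, the metallothionein and zinc transporter list had the largest median at 1 h in HepG2. Of its 11 measured members 6 rose, 0 fell and 5 did not pass, and 8 rose and 2 fell when adjusted over the list alone (median log2 change 2.01, camera adjusted p = 2.5e-11). The transporter genes SLC30A1 and SLC30A10 did not pass. The call was lost when probe sets with the suffix _x_at or _s_at, many of which also match other transcripts of a family, were left out (median 0.58, adjusted p = 0.214), and on another probe set, without such a suffix, MT1G did not pass (log2 change 0.28). Cholesterol synthesis genes shifted upward by a median of 0.40 (adjusted p = 2.7e-05). Of 13, HMGCS1 and IDI1 rose, by 1.01 and 0.89, 0 fell and 11 did not pass, and 3 rose when adjusted over the list alone. In the cell cycle list 25 of 28 members lay above 0 (median 0.33, adjusted p = 2.9e-06), although 0 rose and 0 fell by limma, and 3 rose when adjusted over the list alone. These 3 list calls held with an estimated correlation (adjusted p = 0.0396, 0.0396 and 0.0261). The unfolded protein and ATF4 response list had a median of -0.31 (adjusted p = 0.0189, or 0.127 with an estimated correlation). DDIT4 fell, 15 did not pass and 4 fell when adjusted over the list alone, and the list call was lost without HepG2 untreated replicate 2 (adjusted p = 0.262) and without HepG2 1 h replicate 1 (adjusted p = 0.0625). The complement and coagulation list had a median of -0.22 (adjusted p = 0.0033, or 0.379 with an estimated correlation). C5 fell, 31 did not pass, 1 fell when adjusted over the list alone, and the list call was lost without HepG2 untreated replicate 2, although the median was then -0.29 (adjusted p = 0.262). Of 18 STAT3 early target genes CEBPD, JUNB and IER3 rose, 0 fell and 15 did not pass, with 7 rising and 4 falling when adjusted over the list alone (median 0.10, adjusted p = 0.135). In this list, here and below, SOCS3 counts by the probe set that stands for it and not by the one that rose. Of 18 measured positive acute phase genes none passed in either direction, and 3 rose and 3 fell when adjusted over the list alone (median -0.08, camera adjusted p = 0.562). The haptoglobin gene HP, at 0.96, did not pass (limma adjusted p = 0.16). CRP, SAA1, SAA2, SAA4, ORM2, LRG1 and C9 had no kept probe set with 1 symbol, so the list does not cover them.

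At 4 h in HepG2, the metallothionein genes stayed high. MT1F was at 4208 ± 921 (SD, n = 2), a log2 change of 4.06 (SE 0.28, limma adjusted p = 3.7e-07), and MT1E, MT1G, MT1H, MT1X and MT2A rose by 3.02, 2.85, 2.79, 2.15 and 1.51. CEBPD (1.26), ADM (1.38), AP1M2 (1.74), HMGCS1 (1.26) and IDI1 (0.90) rose as well. The cilium and Wnt antagonist gene CBY1 rose by 2.28 and the DNA repair helicase gene ERCC2 by 1.57. SOCS3 on the probe set that rose at 1 h, at 80.9 ± 50.9, did not pass (log2 change 1.12, adjusted p = 0.54), nor did JUNB (0.39, adjusted p = 0.73) or HP (1.08, adjusted p = 0.075). G6PC1 fell by 2.28 (SE 0.38, adjusted p = 0.0091). FBXO17, the differentiation inhibitor gene ID2, PNISR, ZMIZ1 and STC2 changed by -2.08, -1.52, -1.47, -1.29 and -1.27. The keratin gene KRT23, PTOV1, the MAP kinase phosphatase gene DUSP9 and the receptor gene ERBB3 changed by -1.27, -1.21, -1.21 and -1.20. The metallothionein list had 6 genes up, 0 down and 5 not passing, with 7 up and 1 down when adjusted over the list alone (median 1.73, adjusted p = 7.8e-11). In the cholesterol synthesis list 2 rose, 0 fell and 11 did not pass, with 7 up when adjusted over the list alone (median 0.44, adjusted p = 1.8e-05). In the cell cycle list 0 rose and 0 fell over all genes and over the list alone, and 25 of 28 lay above 0 (median 0.26, adjusted p = 0.0011). These 3 calls held with an estimated correlation (adjusted p = 0.044 for each), but the metallothionein call was lost without the _x_at and _s_at probe sets (adjusted p = 0.356) and the cell cycle call without HepG2 untreated replicate 1 (adjusted p = 0.122). Hepatocyte identity genes shifted downward, with 14 of 17 below 0, 0 called and 2 falling when adjusted over the list alone (median -0.26, adjusted p = 0.0058, or 0.693 with an estimated correlation). That call was also lost with quantile normalization (adjusted p = 0.188) and without HepG2 4 h replicate 1 (0.436). In all, limma called 58 probe sets, 32 up and 26 down, which stood for 41 genes, 21 up and 20 down. The share rising was 55.2% of the probe sets called and 74.1% with a common median. The count was 18 without HepG2 untreated replicate 1, 27 without HepG2 untreated replicate 2, 22 and 27 without HepG2 4 h replicates 1 and 2, and 91 and 95 without dSrc1 1 h replicates 1 and 2. Of the 41 genes, AP1M2, ID2, MT1E, MT1F, MT1G, MT1H and MT1X stayed called whichever array was left out.

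**Figure D2:**
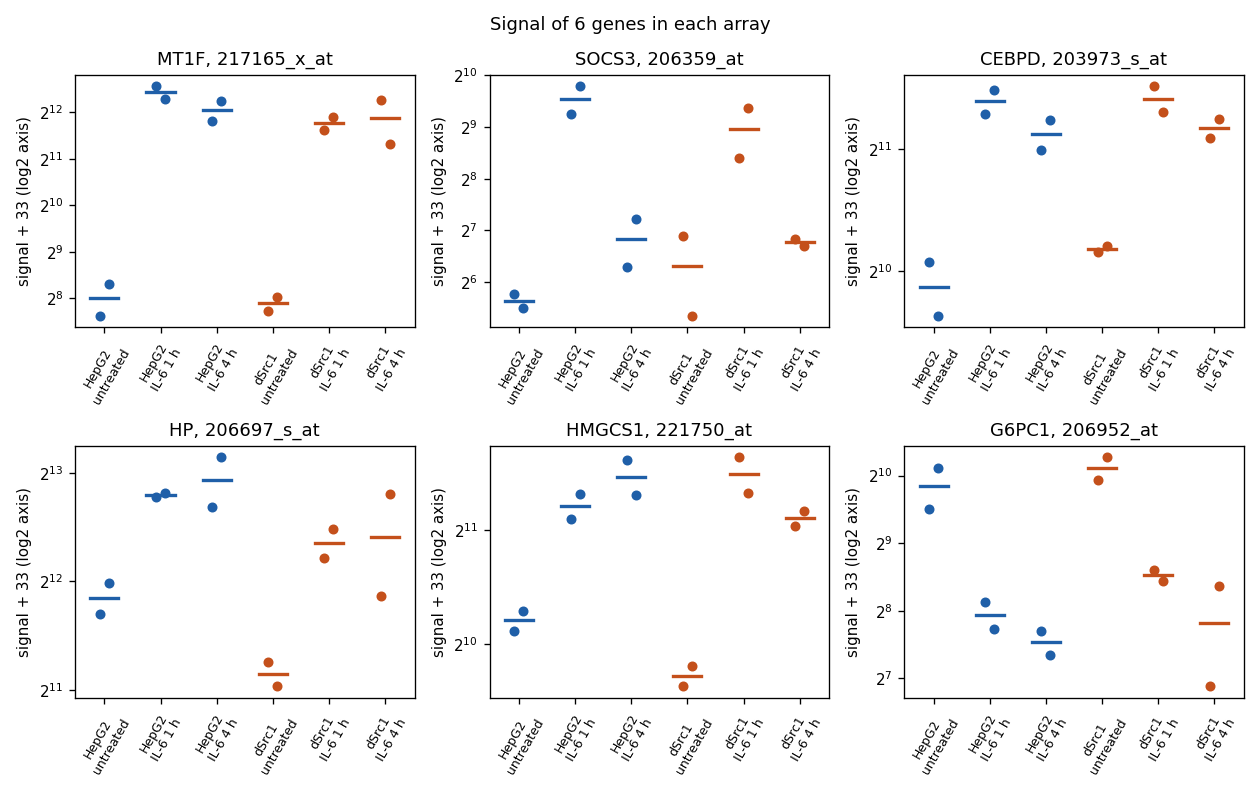
Signal plus 33 (log2 axis) of MT1F, SOCS3 (the probe set that rose at 1 h), CEBPD, HP, HMGCS1 and G6PC1 in untreated cells and after 1 h and 4 h of IL-6. Points are arrays and bars are group means, by line. MT1F in HepG2 went from a mean signal of 225 to 5512 at 1 h, and G6PC1 from 886 to 213.

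The same treatment in dSrc1 asked which of these responses were seen with SRC-1 silenced. At 1 h MT1F went from 204 ± 34.8 to 3444 ± 489 (SD, n = 2 each), a log2 change of 3.87 (SE 0.28, limma adjusted p = 4.1e-07), and MT1E, MT1G, MT1H, MT1X and MT2A rose by 2.98, 2.93, 3.32, 3.26 and 2.41. CEBPD rose by 1.23, ADM as well and AP1M2 by 1.91, and SOCS3 rose by 2.77 on the probe set that rose in HepG2 (SE 0.53, adjusted p = 0.0058). HP rose by 1.20 (SE 0.25, adjusted p = 0.0084), the fibrinogen gene FGB by 0.90 and the STAT5 feedback gene CISH by 1.68. JUNB did not pass (0.89, adjusted p = 0.074). The chemokine gene CXCL2, the sulfotransferase gene SULT1C2 and the galectin gene LGALS2 rose by 2.53, 2.43 and 2.35. ANGPTL8 (-3.90), DDIT4 (-2.88), the complement receptor gene C5AR1 (-2.65), the hepatokine gene INHBE (-2.59) and STC2 (-2.40) had the largest falls. PHF21A, SLC4A2, NRTN, the transsulfuration gene CTH and EEIG1 changed by -2.28, -2.19, -2.16, -2.13 and -2.06. G6PC1 fell by 1.58 (adjusted p = 0.026). Limma called 700 probe sets, 350 up and 350 down, which stood for 464 genes, 229 up and 235 down. The count was 137 without dSrc1 untreated replicate 1 and 250 without dSrc1 untreated replicate 2. Of the 464 genes, 87 and 169 stayed called without these arrays and 68 whichever array was left out, among them the metallothionein genes, CEBPD, HMGCS1, DDIT4, STC2, ANGPTL8 and INHBE. The SOCS3 call was lost without dSrc1 untreated replicate 2 (log2 2.00, adjusted p = 0.103) and without dSrc1 1 h replicate 2 (2.28, adjusted p = 0.0723).

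At 1 h in dSrc1, 15 of 28 cell cycle genes rose, 0 fell and 13 did not pass, with 20 up when adjusted over the list alone (median 0.79, camera adjusted p = 9.6e-16). RRM2, which encodes a subunit of ribonucleotide reductase, rose by 1.78, the replication licensing gene CDC6 by 1.47, the replication clamp gene PCNA by 1.33 and the cyclin gene CCNB1 by 1.25. In the cholesterol synthesis list 10 of 13 rose, 0 fell and 3 did not pass, with 10 up and 1 down when adjusted over the list alone (median 0.93, adjusted p = 3.8e-11). HMGCS1 rose by 1.77, MVD by 1.63, IDI1 by 1.49, FDPS by 1.34 and LSS by 0.93. In the unfolded protein and ATF4 response list 8 of 16 fell, 0 rose and 8 did not pass, with 12 down when adjusted over the list alone (median -0.82, adjusted p = 1.8e-07). DDIT3, TRIB3 and ASNS, targets of the stress transcription factor ATF4, changed by -1.55, -1.34 and -0.88. These 3 calls held with an estimated correlation (adjusted p = 0.0018, 0.0054 and 0.0080). In the metallothionein list 6 of 11 rose, 0 fell and 5 did not pass, with 7 up when adjusted over the list alone (median 2.41, adjusted p = 1.2e-08, or 0.0627 with an estimated correlation). Its call was lost without the _x_at and _s_at probe sets (adjusted p = 0.526). Of 19 immediate early genes 4 fell, 0 rose and 15 did not pass, with 1 up and 6 down when adjusted over the list alone (median -0.40, adjusted p = 0.0338, or 0.223 with an estimated correlation). MYC changed by -1.18 and DUSP1 by -1.44, and the list call was lost without dSrc1 untreated replicate 1 and without either dSrc1 1 h array (adjusted p = 0.208, 0.087 and 0.0677). The coactivator and corepressor list (median -0.35) and the nuclear receptor list (median -0.31) each had an adjusted p of 0.0454, or 0.172 and 0.305 with an estimated correlation. In the former PPARGC1A, a coactivator of gluconeogenesis, fell by 1.05 and 12 did not pass, with 1 down when adjusted over the list alone. In the latter NR0B2 (-1.76) and NR2F1 (-0.90) fell and 16 did not pass, with 2 down when adjusted over the list alone. The coactivator call was lost without any 1 of the 6 dSrc1 arrays (adjusted p = 0.0505 to 0.141), and the nuclear receptor call without either HepG2 1 h array or any dSrc1 array but dSrc1 1 h replicate 2 (0.0528 to 0.373).

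At 4 h in dSrc1, MT1F stood at 3721 ± 1664 (SD, n = 2), a log2 change of 3.92 (SE 0.28, limma adjusted p = 4.6e-07), and MT1E, MT1G, MT1H, MT1X and MT2A rose by 3.25, 2.96, 3.45, 3.11 and 2.24. HP rose by 1.19, CEBPD by 0.99 and AP1M2 by 2.01. The fatty acid transporter gene CD36 rose by 2.31 and the uroplakin gene UPK3A by 2.25. SOCS3 on that probe set (0.64, adjusted p = 0.62) and ADM (0.72, adjusted p = 0.073) did not pass. C5AR1, G6PC1, SLC6A14, STC2 and SLC17A2 had the largest falls, at -2.92, -2.47, -2.39, -2.30 and -2.24. TRAPPC12, NRTN, PKD1, SCARA3 and POGZ changed by -2.12, -2.12, -2.11, -2.04 and -2.04. Limma called 785 probe sets, 339 up and 446 down, which stood for 538 genes, 234 up and 304 down. The count was 132 and 331 without dSrc1 untreated replicates 1 and 2, and 303 without dSrc1 4 h replicate 1, and 70 of the 538 genes stayed called whichever array was left out. Of 18 STAT3 early target genes CEBPD rose, 6 fell and 11 did not pass, with 1 up and 7 down when adjusted over the list alone (median -0.54, camera adjusted p = 3.8e-05). The falling members included EGR1 (-1.47), CEBPB (-1.12), PIM1 (-1.04), CCND1 (-0.82) and VEGFA. Of 19 immediate early genes 6 fell, 0 rose and 13 did not pass, with 8 down when adjusted over the list alone (median -0.58, adjusted p = 5.1e-07). This list and the STAT3 early target list share members, EGR1 among them. Cell cycle genes rose in 10 of 28 cases, 0 fell and 18 did not pass, with 16 up when adjusted over the list alone (median 0.62, adjusted p = 2.2e-11). Cholesterol synthesis genes rose in 8 of 13 cases, 0 fell and 5 did not pass, with 11 up and 1 down when adjusted over the list alone (median 0.81, adjusted p = 1.6e-08). In the unfolded protein and ATF4 response list 7 fell, DNAJB9 rose by 0.89 and 8 did not pass, with 10 down and 1 up when adjusted over the list alone (median -0.91, adjusted p = 1.3e-05). These 5 calls held with an estimated correlation (adjusted p = 0.0306, 0.0238, 0.0045, 0.0113 and 0.0187), and the STAT3 call was lost without the _x_at and _s_at probe sets (adjusted p = 0.111). The metallothionein list (median 2.24, adjusted p = 8.8e-07) had an adjusted p of 0.0685 with an estimated correlation, with 6 up, 0 down and 5 not passing, and 7 up and 2 down when adjusted over the list alone. Its call was also lost without the _x_at and _s_at probe sets (median 0.79, adjusted p = 0.825). The last 4 lists called shifted downward at the preset correlation. They were coactivators and corepressors (median -0.37, adjusted p = 0.0095), nuclear receptors (-0.45, 0.0061), hepatocyte identity (-0.21, 0.0163) and complement and coagulation (-0.39, 0.0163), and with an estimated correlation none passed (adjusted p = 0.0685, 0.152, 0.463 and 0.45). The genes called in them numbered 1, 2, 2 and 6, all falling, and the last 2 calls were lost without dSrc1 4 h replicate 1 (adjusted p = 0.125 and 0.254).

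The comparison of 4 h with 1 h asked whether the response changed over time. Limma called 0 probe sets in HepG2, where 917 had an unadjusted p under 0.05, and 0 in dSrc1, where 985 did. In HepG2, the smallest p-values among the probe sets that stand for a gene belonged to DDIT4 (log2 difference 2.36), TGM2 (1.01), HERPUD1 (0.92), the transcriptional repressor gene HES1 (-1.67) and VAT1 (-0.93). None passed (smallest adjusted p = 0.140). The SOCS3 probe set that rose at 1 h does not stand for its gene and was not ranked here, and it was not called either. In dSrc1, among the probe sets that stand for a gene, they belonged to NRP1 (2.07), ANGPTL8 (1.86), EGR1 (-1.69), GADD45B (-2.37) and HES1 (-1.61), and none passed (smallest adjusted p = 0.111). Over all probe sets the smallest adjusted p in dSrc1 was 0.0527, on another probe set of GADD45B (-2.74). The count in dSrc1 was 60 without dSrc1 1 h replicate 1, 51 without dSrc1 4 h replicate 2, 2 without either of the other arrays of these groups and 1 without HepG2 1 h replicate 2. In HepG2 it was 1 without HepG2 1 h replicate 1, HepG2 4 h replicate 1 or either dSrc1 4 h array. Camera called 0 of 23 lists in HepG2, and fry called 0 in either line. In dSrc1 the positive acute phase (median -0.32, adjusted p = 0.0238), negative acute phase (-0.41, 0.0010), STAT3 early target (-0.30, 0.0010) and immediate early lists (-0.29, 0.0044) were lower at 4 h. With quantile normalization the first 2 calls were lost (median -0.15 and -0.17, adjusted p = 0.12 and 0.0508). No call held with an estimated correlation (adjusted p = 0.457, 0.412, 0.261 and 0.33), and each was lost without at least 1 of HepG2 1 h replicate 1, either dSrc1 1 h array and dSrc1 4 h replicate 1 (adjusted p = 0.051 to 0.697).

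The mean of both lines gave the response to IL-6 with the most arrays behind it. At 1 h limma called 817 probe sets, 390 up and 427 down, which stood for 554 genes, 257 up and 297 down. At 4 h it called 980, 448 up and 532 down, which stood for 650 genes, 304 up and 346 down. HP rose by 1.08 and 1.13 at 1 h and 4 h (limma adjusted p = 0.0011 and 7.4e-04), and FGB by 0.78 at 1 h. CISH rose by 1.62, JUNB by 1.14, the interferon regulatory factor gene IRF1 by 0.96 and EGR1 by 0.80 at 1 h. CXCL2 rose by 2.16 and the disulfide isomerase gene AGR2 by 1.77 at 1 h, and the tryptophan pathway gene HAAO by 1.48 at 4 h. MT1M, measured on a probe set without the suffix _x_at or _s_at, rose by 1.81 and 1.70 (adjusted p = 0.035 and 0.042), while the zinc importer gene SLC39A4 changed by -0.49 and -0.51. The positive acute phase list was not called (median -0.13 and -0.22, camera adjusted p = 0.839 and 0.216). Of its 18 measured members, without CRP and the SAA genes, 2 rose and 2 fell at 1 h, and 1 rose and 6 fell at 4 h. When adjusted over the list alone, 4 rose and 3 fell at 1 h, and 5 rose and 8 fell at 4 h. Among acute phase genes that fell, the ceruloplasmin gene CP changed by -0.86 and -0.68 and ITIH3 by -0.82 and -0.86, and at 4 h SERPINA3 changed by -0.63, HAMP, which encodes the iron hormone hepcidin, by -0.95 and CFB by -0.62. Camera called 6 lists at 1 h and 9 at 4 h. The cell cycle (median 0.57 and 0.46) and cholesterol synthesis lists (0.73 and 0.66) rose at both times, and at 1 h the metallothionein list rose (2.21) and the ATF4 list fell (-0.54), and only these 6 calls held with an estimated correlation (adjusted p = 0.0022 to 0.0441). The metallothionein call at 1 h was lost without the _x_at and _s_at probe sets (median 0.29, adjusted p = 0.26). RGCC (-1.97) and SYNGR3 (-1.65) fell at 1 h, and WDR13 (-1.68) and RAB17 (-1.59) at 4 h. The 1 h count was 433 and 531 without HepG2 untreated replicates 1 and 2, 377 and 424 without the HepG2 1 h arrays, and 343 and 422 without the untreated dSrc1 arrays. The 4 h count was 516 without HepG2 untreated replicate 1, 567 and 634 without the HepG2 4 h arrays, 392 and 614 without the untreated dSrc1 arrays, and 605 without dSrc1 4 h replicate 1. Of the genes, 175 at 1 h and 231 at 4 h stayed called whichever array was left out.

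The lists not given above are reported for the mean of both lines, at 1 h and then 4 h. None of the following was called by camera. Negative acute phase genes had medians of 0.16 and -0.16, with 0 of 12 called at either time. IL-6 receptor and JAK-STAT components had medians of -0.15 and -0.03, with CISH up at 1 h, 18 of 19 not passing then and 0 called at 4 h. Interferon-stimulated genes had medians of -0.17 and 0.12, with IRF1 up at 1 h, 17 of 18 not passing then and 0 called at 4 h. NF-kappaB target genes had medians of -0.35 and -0.17, with CXCL2 up and CCL20 down at 1 h and NFKBIA and CCL20 down at 4 h, of 14. Nuclear receptor target genes had medians of -0.32 and -0.33, with G6PC1 down at both times (-1.73 and -2.38) and 11 of 12 not passing. In the drug metabolism list, with medians of -0.36 and -0.03, GSTA1 rose and CYP1A1 fell at both times and 13 of 15 did not pass. In the iron handling list, with medians of 0.11 and -0.06, HMOX1 rose and TFR2 and CP fell at 1 h, ACO1 rose and HAMP and CP fell at 4 h, and 8 of 11 did not pass at either time. In the hypoxia and glycolysis list, with medians of 0.13 and 0.05, ADM rose at both times, BNIP3 at 4 h, and VEGFA and NDRG1 fell at both, of 15. Fibroblast markers had medians of 0.06 and -0.08 (PDGFRB down at 4 h, of 9), leukocyte markers 0.16 and 0.05 (0 of 6 called), endothelial markers 0.27 and 0.09 (0 of 3 called) and cholangiocyte markers -0.07 and 0.19 (SPP1 up at both times and CD24 down at 1 h, of 6). Adjusted over the list alone, 0 genes were called in the negative acute phase, leukocyte and endothelial lists. Of 276 list tests over 12 contrasts, camera called 73, and 33 with an estimated correlation.

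**Figure D3:**
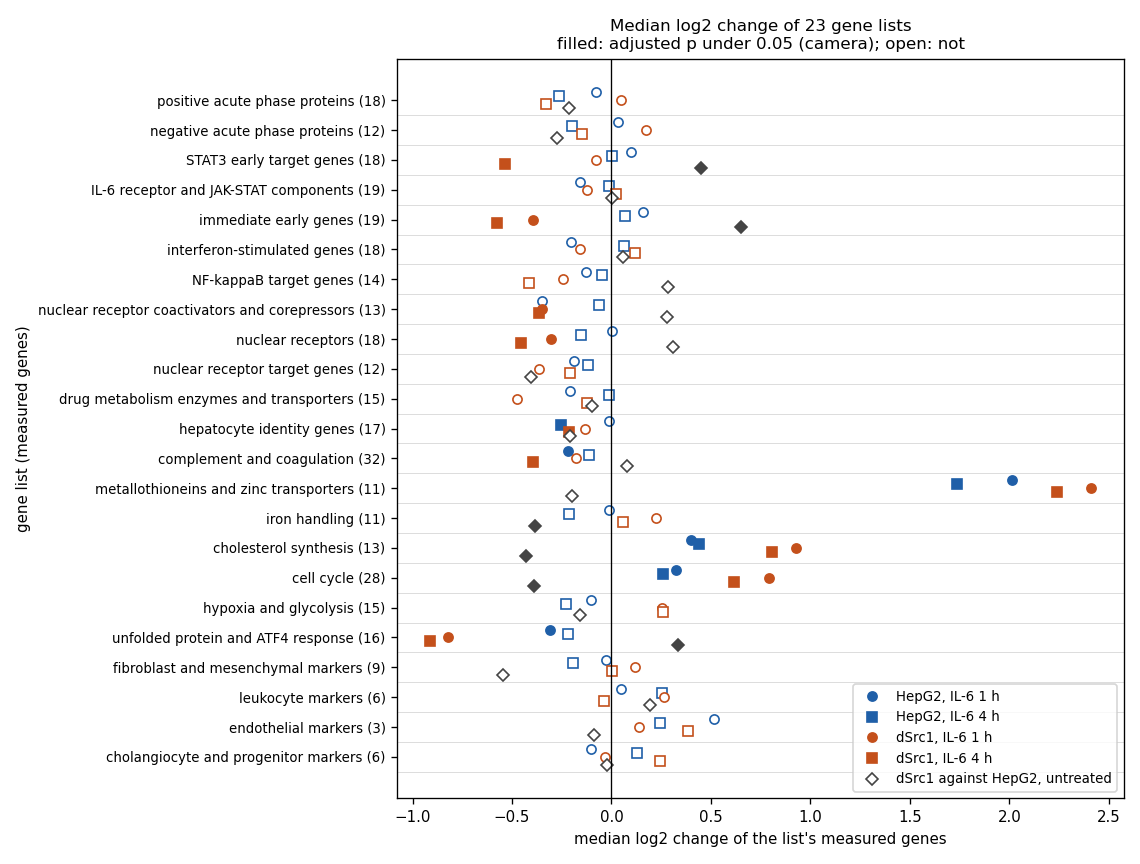
Median log2 change of each of the 23 gene lists for IL-6 at 1 h and 4 h in HepG2 and dSrc1 and for untreated dSrc1 against HepG2. Filled symbols have a camera adjusted p under 0.05 at the preset correlation. The metallothionein list lies at 2.01 and 1.73 in HepG2 and at 2.41 and 2.24 in dSrc1.

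Most genes called in HepG2 were also called in dSrc1, while most genes called in dSrc1 were not called in HepG2. No array belongs to both lines, so their calls share only the estimate of the spread. Genes are not independent of one another, however, so the p-values of Fisher's exact test give no exact chance level. The genes that rose in both lines at both times include MT1E, MT1F, MT1G, MT1H, MT1HL1, MT1X and MT2A. These were measured on _x_at probe sets, many of which also match other transcripts of a family. Of 21 genes that rose at 1 h in HepG2 and 229 in dSrc1, 18 rose in both, against 0.496 expected (Fisher's exact test, one-sided, p = 3.4e-27, adjusted 1.4e-26), and of 12 and 235 that fell 11 fell in both, against 0.291 (p = 1.6e-17). At 4 h 16 of 21 and 234 rose in both, against 0.507, and 17 of 20 and 304 fell in both, against 0.628 (Fisher's exact test, p = 1.5e-22 and 1.9e-23). Across all 9688 genes, which are not independent replicates, Pearson's r of the HepG2 and dSrc1 changes was 0.300 at 1 h and 0.297 at 4 h.

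Whether silencing SRC-1 altered the response to IL-6, the purpose of the series, was tested as the interaction of line and treatment. For single genes almost nothing passed. Limma called 0 probe sets at 1 h, where 1046 had an unadjusted p under 0.05, and 1 at 4 h, where 1099 did. SOCS3 on the probe set that rose (-1.12 at 1 h, adjusted p = 0.90), CEBPD (-0.30, 0.93), JUNB (-0.51, 0.91), HP (0.25, 0.96) and MT1F (-0.59, 0.90) did not differ detectably between lines. The smallest p-values at 1 h belonged to RPA3 (1.25), SUGCT (2.82), the replication gene GINS2 (1.77), CD6 (2.83) and INHBE (-1.82), and at 4 h, among genes, to the catalase gene CAT (1.24), ACAT2 (1.30), RPA3 (1.24), TGFB1 (-1.67) and PKD1 (-3.02), and none of these passed. The probe set called at 4 h has no gene symbol. Its difference was 2.64 (SE 0.37, adjusted p = 0.0224), and it was also lower in untreated dSrc1 than in untreated HepG2 (-2.13, adjusted p = 0.0036). The 4 h count was 4 without dSrc1 untreated replicate 2, 23 without dSrc1 4 h replicate 2, and 0 without HepG2 untreated replicate 1, HepG2 4 h replicate 1, dSrc1 untreated replicate 1, dSrc1 4 h replicate 1 or either HepG2 1 h array, and the 1 h count was 2 without dSrc1 1 h replicate 2.

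Gene lists did differ in their response between lines. At 1 h the response of the cholesterol synthesis (median difference 0.60, camera adjusted p = 1.6e-05) and cell cycle lists (0.44, 1.6e-06) was higher in dSrc1. That of the immediate early (-0.73, 8.2e-06) and the unfolded protein and ATF4 lists (-0.31, 4.2e-04) was lower. At 4 h the cell cycle list (0.38, 7.0e-06) was again higher and the STAT3 early target (-0.64, 1.1e-05), immediate early (-0.74, 5.5e-06) and ATF4 lists (-0.52, 1.1e-05) lower. These 8 calls held with an estimated correlation (adjusted p = 0.0208 to 0.0356), but the 4 h STAT3 call was lost without the _x_at and _s_at probe sets (median -0.27, adjusted p = 0.38). The STAT3 early target and immediate early lists share FOS, JUNB, EGR1, IER3, KLF6, ZFP36 and MYC, so their calls are not separate results. Calls that did not hold were STAT3 early targets (-0.49, 8.9e-04, estimated 0.0649), nuclear receptors (-0.38, 0.0462, estimated 0.323), iron handling (0.24, 0.0462, estimated 0.143) and hypoxia and glycolysis (0.25, 0.0462, estimated 0.141) at 1 h, and coactivators and corepressors (-0.30, 0.0296, estimated 0.125), nuclear receptors (-0.47, 0.0246, estimated 0.23) and cholesterol synthesis (0.37, 0.0073, estimated 0.0957) at 4 h. The positive acute phase list did not differ detectably (median 0.14 and -0.10, adjusted p = 0.568 and 0.432), nor did the metallothionein list (0.22 and 0.11, adjusted p = 0.92 and 0.533). No list member passed over all genes in either interaction. Each list difference also holds the untreated line difference with the opposite sign. In untreated cells the cell cycle and cholesterol synthesis lists were lower in dSrc1, and the immediate early, STAT3 early target and ATF4 lists higher. With IL-6, camera called 0 lists between the lines at 1 h and 2 at 4 h, which were the acute phase lists. The list calls thus do not separate an altered response from a different untreated state. The log2 difference of RRM2 at 1 h and 4 h was 0.65 and 0.63 in HepG2 and 1.78 and 1.62 in dSrc1. That of TRIB3 was -0.46 and -0.26 against -1.34 and -1.27, and that of DDIT3 -0.23 and -0.18 against -1.55 and -1.36. The HepG2 values did not pass.

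Over the 554 genes called for the mean of both lines at 1 h, the median response was 0.54 in HepG2 and 0.91 in dSrc1. The median difference was 0.36, and 81.2% of the genes responded more in dSrc1 (rotation test, adjusted p = 4.9e-04). At 4 h, over 650 genes, the medians were 0.53 and 0.90, the difference 0.34 and the share 81.2% (rotation test, adjusted p = 0.0023). Rising and falling genes each gave a difference in the same direction, at 1 h 0.42 and 0.32 and at 4 h 0.32 and 0.36. Both times are set against the same untreated arrays, so their results are not independent of each other. Genes called in 1 line favour that line by construction. The difference was 0.108 over the 33 genes called in HepG2 at 1 h (adjusted p = 0.839) and -0.0231 over the 41 at 4 h (adjusted p = 0.824), and 0.614 over the 464 called in dSrc1 at 1 h (adjusted p = 2.6e-05) and 0.629 over the 538 at 4 h (adjusted p = 1.3e-04), so neither pair measures the difference without this bias. Over the positive acute phase and STAT3 early target genes it was 7e-04 at 1 h (adjusted p = 0.98) and 0.208 at 4 h (adjusted p = 0.0081). Among these the rising genes gave -0.15 (16 genes, adjusted p = 0.42) and -0.12 (10 genes, adjusted p = 0.282), and the falling ones 0.08 (20 genes, adjusted p = 0.12) and 0.34 (26 genes, adjusted p = 0.0108), so that only the falling genes at 4 h passed. Over the genes called for the mean of both lines, the 4 h difference was 0.215 and no longer passed without HepG2 untreated replicate 2. That difference was 0.516 and 0.534 without dSrc1 untreated replicate 2 and dSrc1 4 h replicate 2. The 1 h difference over the genes called for this mean was 0.554 without dSrc1 untreated replicate 2.

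**Figure D4:**
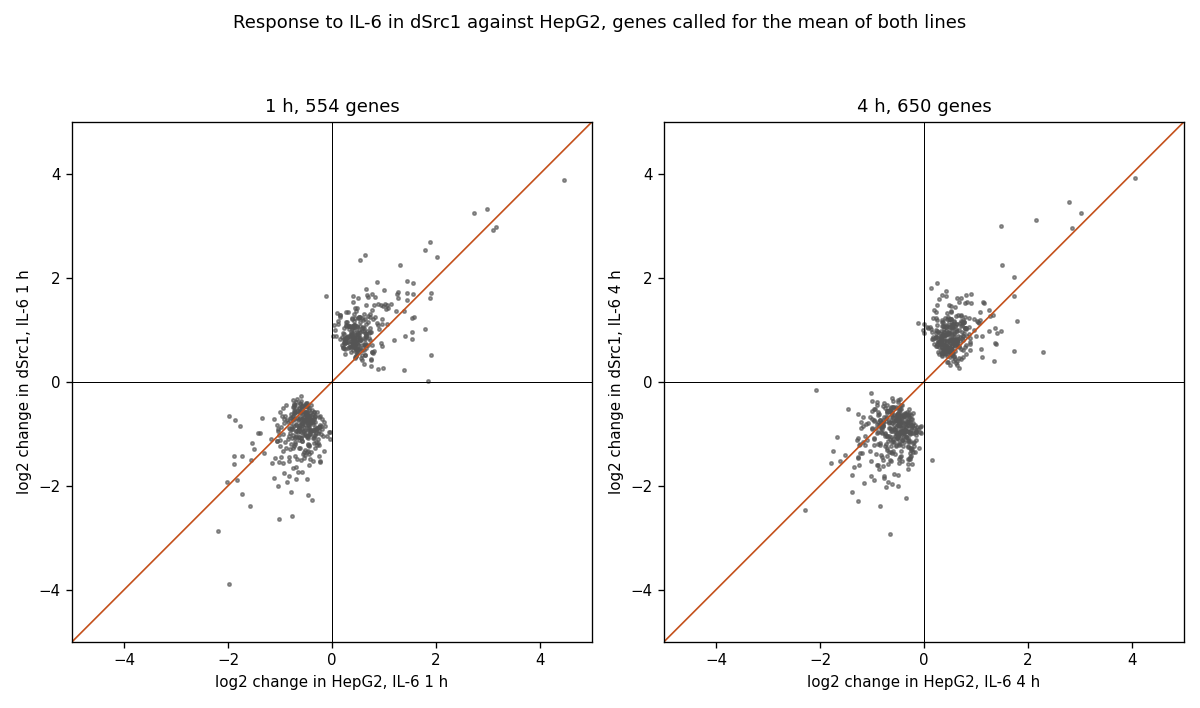
Log2 change after IL-6 in dSrc1 against that in HepG2, at 1 h for 554 genes and at 4 h for 650 genes called for the mean of both lines. Each point is a gene and the line marks equal responses. At both times 81.2% of the genes responded more in dSrc1.

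Untreated dSrc1 and untreated HepG2 were compared to learn how the lines differed before IL-6. Cell cycle genes were lower in untreated dSrc1, with 24 of 28 below 0, RRM2 (-1.14) and TYMS (-0.81) called, 26 not passing and 12 lower when adjusted over the list alone (median -0.39, camera adjusted p = 4.9e-09). Cholesterol synthesis genes were lower in 12 of 13 cases, with FDPS (-1.15) called, 12 not passing and 6 lower when adjusted over the list alone (median -0.43, adjusted p = 3.3e-05). The immediate early list was higher in 18 of 19 cases, with 0 called and 7 higher when adjusted over the list alone (median 0.65, adjusted p = 2.55e-06). The STAT3 early target list, which shares members with the immediate early list, was higher in 16 of 18 cases. In it 0 were called and 6 were higher when adjusted over the list alone (median 0.45, adjusted p = 3.2e-05). In the unfolded protein and ATF4 response list 15 of 16 were higher, with TRIB3 (0.88) called, 15 not passing and 4 higher when adjusted over the list alone (median 0.34, adjusted p = 3.3e-05). These 5 calls held with an estimated correlation (adjusted p = 0.0086 to 0.0255), and the STAT3 call was lost without the _x_at and _s_at probe sets (adjusted p = 0.382). The iron handling call (median -0.39, adjusted p = 0.0476) did not hold (adjusted p = 0.151 with an estimated correlation) and was lost without any 1 of the untreated arrays, the HepG2 1 h arrays and dSrc1 4 h replicate 1 (0.0534 to 0.116). Among single genes, the mitochondrial calcium channel gene MCUB (2.65), the thiamine transporter gene SLC19A3 (2.06), ERCC2 (1.86), INHBE, TGFB1 (1.38), the cystine transporter gene SLC7A11 (1.25), IFRD1 (1.15), ITIH3 (1.08), C5 (1.01) and FILIP1L (0.97) were highest in dSrc1 relative to HepG2. SUGCT (-2.18), the metallothionein-like gene MT1HL1 (-1.89), LGALS2 (-1.82), FKBP10 (-1.57), the deiodinase gene DIO1 (-1.43), RPA3 (-1.25), CETN2 (-1.22), GM2A (-1.19), FDPS and RRM2 were lowest. Limma called 47 probe sets, 18 higher (38.3%) and 29 lower, which stood for 33 genes, 13 higher and 20 lower. With a common median 1 was called, which was lower. The count was 0 and 21 without HepG2 untreated replicates 1 and 2, 1 and 6 without dSrc1 untreated replicates 1 and 2, 4 without either HepG2 1 h array, 21 without either HepG2 4 h array, and 113 and 110 without dSrc1 1 h replicates 1 and 2. None of the 33 genes stayed called whichever array was left out.

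As the mean of 3 treatments, dSrc1 differed from HepG2 in 41 probe sets, 22 higher (53.7%) and 19 lower. Those that stand for a gene gave 28 genes, 17 higher and 11 lower. The called NCOA1 probe set does not stand for its gene, so NCOA1 is not among the 28. The fast troponin gene TNNI2 was higher in dSrc1. Its signal was 12.4 ± 3.39 in untreated HepG2 and 153 ± 19.1 in untreated dSrc1, and 12.7 ± 0.707 and 313 ± 28.6 at 4 h (SD, n = 2 each; log2 difference 2.64, SE 0.27, limma adjusted p = 2.9e-04). The HepG2 signals lie below the offset of 33, so the size of this difference depends on the offset. MCUB (2.06), FGL1 (0.94), DEPP1 (0.76), the Wnt antagonist gene DKK1 (0.74), OPTN (0.68), SOBP (0.66), TIMP3 (0.65), SERTAD2 (0.63) and FST (0.62) were higher. The heterochromatin protein gene CBX5 (-1.32), MT1HL1 (-1.12), LGALS2 (-1.05), GSTA1 (-0.81), DIO1 (-0.79), SOX4 (-0.76), the carboxylesterase gene CES1 (-0.74), PPP1CB (-0.66), CETN2 (-0.61) and COPE (-0.59) were lower. At the preset correlation camera called 7 lists, all lower in dSrc1. The negative acute phase list had a median of -0.26, with 0 of 12 called and 0 when adjusted over the list alone (camera adjusted p = 0.0020). The positive acute phase list had a median of -0.18 (0.0163), with 1 of 18 higher, 0 lower and 17 not passing, and 1 higher and 3 lower when adjusted over the list alone. The hepatocyte identity list had a median of -0.20 (0.0101), with 0 of 17 called and 1 lower when adjusted over the list alone. The nuclear receptor target (-0.20, 0.0101), metallothionein (-0.33, 0.0038), cholesterol synthesis (-0.14, 0.037) and cell cycle lists (-0.16, 4.4e-04) were lower too. None of these 7 calls held with an estimated correlation (adjusted p = 0.357, 0.479, 0.395, 0.357, 0.357, 0.357 and 0.0677), and the first 3 were lost with quantile normalization and without dSrc1 1 h replicate 1 (adjusted p = 0.059 to 0.166). With a common median 5 probe sets were called, of which 80% were higher. The count was 7 and 5 without HepG2 untreated replicates 1 and 2, 6 and 4 without the HepG2 1 h arrays, 11 and 7 without the HepG2 4 h arrays, 5 and 10 without the untreated dSrc1 arrays, 63 and 115 without dSrc1 1 h replicates 1 and 2, and 26 and 81 without dSrc1 4 h replicates 1 and 2. TNNI2, MCUB, FGL1 and MT1HL1 stayed called whichever array was left out. Within the IL-6 arrays, a comparison chosen after seeing the data, limma called 0 probe sets at 1 h (1195 with an unadjusted p under 0.05) and 0 at 4 h (629), and as the mean of both times TNNI2 (2.95), FGL1 (0.94) and DKK1 (0.90) were higher. Camera called 0 lists at 1 h, 2 at 4 h and 4 for the mean of both times, all lower in dSrc1, and 0 with an estimated correlation. At 4 h these were the positive and negative acute phase lists (median -0.26 for each, adjusted p = 0.0015 for each), and fry called 0 lists in all 3 comparisons.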

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

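All tests of explanations in this part were chosen after the result they address was seen.

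Gene lists whose response to IL-6 differed between dSrc1 and HepG2 by camera on the interaction were picked out because the difference itself was tested. At 1 h the median difference (dSrc1 response minus HepG2 response, log2) was 0.60 for cholesterol synthesis, 0.44 for the cell cycle, 0.25 for hypoxia and glycolysis and 0.24 for iron handling. It was -0.49 for STAT3 early targets, -0.73 for immediate early genes, -0.38 for nuclear receptors and -0.31 for the unfolded protein and ATF4 response. At 4 h it was 0.37 for cholesterol synthesis, 0.38 for the cell cycle, -0.64 for STAT3 early targets, -0.74 for immediate early genes, -0.30 for nuclear receptor coactivators and corepressors, -0.47 for nuclear receptors and -0.52 for the unfolded protein and ATF4 response. With an estimated correlation 4 of the 8 calls at 1 h and 4 of the 7 at 4 h held. The lists of these calls differed in the opposite direction between untreated dSrc1 and untreated HepG2, so the calls are not separate from that difference. The STAT3 early target and immediate early calls also rest in part on the same genes. Each of the 12 arrays, left out alone, ended at least 1 of the nuclear receptor, iron handling, hypoxia and coactivator calls (adjusted p = 0.055 to 0.473), and the 4 h cholesterol synthesis call without dSrc1 untreated replicate 1 (adjusted p = 0.1003). Both STAT3 calls were lost without the _x_at and _s_at probe sets (adjusted p = 0.38 at 4 h), and the 1 h call also without the 2 arrays that stand apart (adjusted p = 0.169).

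The only probe set called for the interaction, at 4 h, has no gene symbol, and its response was 2.64 higher in dSrc1 (SE 0.37). Its log2 difference after IL-6 was -1.20 in HepG2 (adjusted p = 0.059) and 1.44 in dSrc1 (adjusted p = 0.0039), so that only the rise in dSrc1 passed. The call was lost without HepG2 untreated replicate 1, HepG2 4 h replicate 1, dSrc1 untreated replicate 1, dSrc1 4 h replicate 1 or either HepG2 1 h array, when 0 probe sets were called. No explanation was tested for it.

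The median response over the genes called for the mean of both lines was larger in dSrc1 by 0.36 at 1 h and by 0.34 at 4 h (log2). Both values are taken against the same untreated arrays and are not independent. This larger response was picked out because the rotation test of the difference passed at both times. The HepG2 untreated array that stood apart does not account for it, since without that array the smaller of both differences was 0.386, although without HepG2 untreated replicate 2 the 4 h difference was 0.215 and no longer passed. A different untreated state of the dSrc1 cells is a candidate explanation: signed by the response, dSrc1 differed from HepG2 by -0.36 and -0.30 in untreated arrays (the 1 h and 4 h genes), but by at most 0.055 in the IL-6 arrays. In that reading these genes differed, in the median, mainly before IL-6, with lower cell cycle and cholesterol synthesis genes and higher immediate early and ATF4 genes in untreated dSrc1, although TNNI2, FGL1 and DKK1 differed between the lines in the IL-6 arrays as well. Whether that state came from the loss of SRC-1 or from another property of the shRNA line cannot be told apart, because the design holds 1 silenced line and none with a control shRNA, and the handling of the untreated cultures stays open as well.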

How the results depend on the processing

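Of 32 settings, 1 was added after seeing the data: leaving out 2 arrays that stand apart. No paired analysis was possible because the labels carry no replicate numbers that link arrays of different groups. Of 293 called gene results 220 were lost under at least 1 setting and 0 reversed, and of 73 called list results 47 were lost and 0 reversed. The stricter filter gave no value for NCOA1 on 2 of its probe sets, including the called one. With 2 arrays per group and an offset of 33, changes of genes near that signal are compressed. Where an array is left out, the lone array of its group is assumed to vary like the others. No setting moved the median of all genes by over 0.1. Except where stated, the cause was not tested.

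Counts of probe sets called that moved by over 1.5 times are given by setting. With double the offset 4 h against 1 h in dSrc1 gave 1. With no offset and a floor of 1 the mean line difference gave 22. With quantile normalization 4 h against 1 h in dSrc1 gave 1 and the 4 h interaction 2. With a common median IL-6 gave 26 and 27 in HepG2 at 1 h and 4 h, 282 and 315 in dSrc1 and 334 and 445 for both lines, 4 h against 1 h in dSrc1 gave 1, the untreated line difference 1 and its mean 5, and NCOA1 was at -1.60 and no longer passed. Without a filter, which tests more probe sets, HepG2 at 1 h gave 25, the 4 h interaction 0, the untreated line difference 6 and its mean 17. Without the trend IL-6 gave 15 and 3 in HepG2, 81 and 83 in dSrc1 and 139 and 160 for both lines, 4 h against 1 h in dSrc1 gave 1, the 4 h interaction 0, the untreated line difference 0 and its mean 2. With array weights the untreated line difference gave 110. With at least 2-fold as well, a stricter rule by construction, IL-6 gave 384 and 407 in dSrc1 and 183 and 196 for both lines, and the mean line difference 8. With an adjusted p under 0.1, a looser one, IL-6 gave 70 and 96 in HepG2, 1090 and 1194 in dSrc1 and 1257 for both lines at 1 h, 4 h against 1 h in dSrc1 gave 1, the untreated line difference 100 and its mean 86. With the mean of a gene's probe sets the mean line difference gave 24. Without _x_at and _s_at probe sets, hence with fewer tested, IL-6 gave 16 and 12 in HepG2, 280 and 295 in dSrc1 and 332 and 387 for both lines, and 47 list tests were called. With an estimated correlation 33 list tests were called. Without the 2 arrays that stand apart IL-6 gave 26 and 22 in HepG2, 458 in dSrc1 at 1 h and 385 for both lines at 1 h, the 4 h interaction 0 and the untreated line difference 0. With only the 6 arrays of the line IL-6 gave 76 and 101 in HepG2 and 324 and 363 in dSrc1, and 4 h against 1 h gave 9 in HepG2.

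The response size reversed over the genes called in HepG2 at 4 h (-0.0231) and no longer passed over those called at 1 h (0.108). Over the genes called in dSrc1 it was 0.614 at 1 h and 0.629 at 4 h. Choosing genes by the response of 1 line favours that line by construction, so these sets show neither a reversal nor an increase. It no longer passed over the acute phase and STAT3 lists at 1 h (7e-04). It passed under every other setting at 1 h.

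With each array left out in turn, the ranges were 19 to 70 for IL-6 at 1 h in HepG2, 18 to 95 at 4 h, 137 to 873 and 132 to 1088 in dSrc1, 343 to 1089 and 392 to 1324 for both lines, 0 to 1 for 4 h against 1 h in HepG2, 0 to 60 in dSrc1, 0 to 2 and 0 to 23 for the interaction at 1 h and 4 h, 0 to 113 for the untreated line difference and 4 to 115 for its mean. NCOA1 ranged from -1.69 to -1.53 and lost its call in 9 of 12 cases, and the response size at 4 h ranged from 0.215 to 0.534, losing its call without HepG2 untreated replicate 2.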

Other observations

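All tests of explanations in this part were chosen after the result they address was seen, except the counts over other splits of the arrays, which were fixed before.

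The calls for the mean of both lines were set against other splits of the same arrays. With line as a block and only the 8 arrays of the comparison, 1 of 35 splits, the real one, gave as many calls as the real split at 1 h (659 probe sets, highest other 0). At 4 h 1 of 35 splits did (977 probe sets, highest other 0). Every other split mixes treated and untreated arrays, so the IL-6 difference widens its spread and few calls could arise. For dSrc1 against HepG2, with treatment as a block and 12 arrays, 1 of 100 splits did (17 probe sets, highest other 9). These 100 were the real split and a random draw from the other splits, of 462 in all. In each case the real split gave more calls than any other tried. Chance is not excluded, because the arrays of a group may not come from separate cultures. These counts of calls differ from those of the report because the blocked fits hold other terms and arrays.

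As the mean of both lines, the metallothionein, cholesterol synthesis and cell cycle lists moved upward and the ATF4 list downward after IL-6, at 1 h and at 4 h, although with an estimated correlation the metallothionein and ATF4 calls at 4 h were lost (adjusted p = 0.0675 and 0.0635), and in HepG2 alone the ATF4 list was not called at 4 h. The tables argue against a single divergent untreated array as the source of the shift in this mean, since with any of the 4 untreated arrays left out each list kept at least 81.5% of it. For the ATF4 list in HepG2 alone at 1 h such an array stays open, since without HepG2 untreated replicate 2 its median went from -0.31 to -0.20 and its call was lost (adjusted p = 0.262). A difference in handling between untreated and treated cultures, such as a change of medium, could give a step common to all treated cultures, and as the mean of both lines the largest change from 1 h to 4 h was 22.3% of the 1 h shift. Handling and IL-6 cannot be told apart for these lists, because no culture without IL-6 was handled alike at 1 h or 4 h.

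For dSrc1 against HepG2 as the mean of 3 treatments, camera called the negative acute phase, positive acute phase and hepatocyte identity lists lower at the preset correlation, with medians of -0.26, -0.18 and -0.20. With an estimated correlation none of these calls held (adjusted p = 0.357, 0.479 and 0.395), and 0 of 12 negative acute phase genes were called. Unequal signal distributions of the arrays under the authors' scaling may account for this. After quantile normalization the medians were -0.076, -0.0541 and -0.0848, and no list passed (adjusted p = 0.211, 0.258 and 0.258). A lower level of these transcripts in dSrc1 is not excluded, since quantile normalization would also remove a real shift shared by the brightest genes, and this was not tested.

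The ratio of 3' to 5' signal lay between 1.21 and 1.56 for actin and between 1.01 and 1.16 for GAPDH in the 12 arrays. In each of the 6 groups the array listed first had the higher ratio for actin, by 1.26 to 1.23 at the least and 1.51 to 1.21 at the most. It also had the lower ratio for GAPDH in each group, by 1.1592 to 1.1594 at the least and 1.01 to 1.15 at the most. The cause was not tested. Since each group holds 1 array of each kind, this difference does not separate the groups. If it marks a batch, it adds to the spread that every test uses. The highest signal of an array was 39303 in HepG2 untreated replicate 1 and 46643 in dSrc1 1 h replicate 2, the arrays that stood apart, and 21855 to 36393 in the others.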
